A study of Mus musculus with 10 samples.

How the data were processed

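RNA was taken from the left atrium of adult mice, 4 labelled control and 6 labelled Tbx5 knockout, and sequenced as single-end reads of 51 bp, per the labels' protocols. Globin RNA was depleted before library preparation, per the labels, so counts of globin genes do not measure blood. The labels' protocols name both an mRNA library kit and ribosomal-depleted total RNA, so it stays open which of these the libraries were. Per the submitters' processing notes, the tools were FastQC, TopHat2 2.0.11, featureCounts and DESeq2, and the genome build was mm10. The gene annotation, the strand setting of the counting and the treatment of reads that fit several genes are not given in the sources used here. Overlapping or antisense genes, histone copies and other paralogs may therefore share reads.

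The authors deposited raw counts per gene symbol and library, per the file headers, and these whole numbers were used as they stand. The authors also deposited a normalized signal per gene and library, the count divided by 1 size factor per library, per the file headers and as checked on the values. The log2 fold change and its standard error in the deposited table are the authors' own comparison of knockout with control. A linear fold, deposited beside it, is 2 to the power of that log2 value. The p-value and adjusted p-value in the deposited table come from the authors' DESeq2 comparison, per the file headers and processing notes. All columns of per-sample values matched a library by its label.

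Samples were grouped by their titles. Gene positions came from GENCODE M21, which is on GRCm38, the assembly also called mm10, matched by gene symbol. Ifltd1 and Cyr61 had no match and have no position here. Levels in the text are the deposited normalized counts, as mean ± SD.

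Tests used edgeR 4.0.16 in R 4.3.3 on the raw counts. Genes were kept by filterByExpr with the 2 groups, libraries were scaled by TMM, and the quasi-likelihood F-test was applied with Benjamini-Hochberg adjustment at 0.05 over 13191 genes. The standard error of a log2 fold change was taken as its absolute value divided by the square root of F. The genotype effect was fitted on all 10 libraries without covariates. Effects within each labelled sex, their difference and the sex difference came from fits with sex and group. The Tbx5 level had an exact permutation test. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members, and members were also counted when adjusted over the list alone. The test functions were first checked on simulated counts for 13191 genes with 200 changed. For the genotype effect 34.3% of 1.5-fold, 70.1% of 2-fold and 97.0% of 4-fold changes were recovered, with 11 false calls among 145. For the interaction these shares were 0%, 13.4% and 78.8%, with 6 false calls among 67. The list test recovered 1 of 1 shifted lists and called 0 others. Genes were drawn independently in that run, so it does not check whether the preset correlation suits these data.

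The groups, tests, gene lists and the rule for named genes were set before the data were examined. Named genes are Tbx5, then the 12 largest rises and the 12 largest falls past the threshold in which every knockout library lay beyond every control library. Those needed a mean of at least 50 normalized counts in the higher group and a symbol other than that of a predicted gene. Up to 4 members of each list with the smallest adjusted p, and up to 6 genes each for the interaction and the sex difference, complete the rule. Some genes that the rule names are not reported here. Symbols of a list that were not in the table were dropped.

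Total counts ran from 5701670 to 7697556 per library, so a gene with a few reads per library has a large counting error. Pearson correlations of log2 CPM values were 0.964 to 0.986 within groups and 0.888 to 0.949 between them. No replicates agreed within sampling noise, since the lowest chi-square per degree of freedom within a group was 4.34. The first principal component of the 1000 most variable genes held 73.4% of their variance and separated the groups. The labels name separate animals, and no batch, date or litter is given for any library.

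Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0 and limma-voom, no filter or at least 50 counts in at least 4 libraries, sex or a replicate block as covariates, an adjusted p of 0.1, an absolute log2 fold change above 1, a test against a fold of 1.2, camera with an estimated correlation, fry, fits from 1 labelled sex alone, and each library left out in turn. Alternatives chosen after the data were seen were scaling to library size only, a robust quasi-likelihood fit, leaving out control F1 and knockout M3 together, and offsets for GC content and exon length. The last used 11973 genes (90.8% of those tested) with an annotated exon length and GC content. These offsets were fitted to each library without regard to group. A real genotype change that follows length or GC content would thus be removed with any bias. Pseudocount alternatives planned for normalized values were not needed, because counts were deposited.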

Results

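Left atrial tissue from adult mice was profiled by RNA sequencing in 10 libraries, 4 labelled control and 6 labelled Tbx5 knockout. Tbx5 encodes a T-box transcription factor of the heart. In the knockout, a tamoxifen-inducible Cre recombinase expressed from the ubiquitous Rosa26 locus removed exon 3 of Tbx5. Tamoxifen was injected at 0.167 mg per day for 3 days, and tissue was taken 1 week later. The animals were of mixed C57B6 and 129 background, with an age given as 8 to 10 weeks in the sample labels and as 6 to 8 weeks in the extraction protocol. Control libraries were labelled wild type for Tbx5. The labels used here do not say whether the controls received tamoxifen or carried the Cre allele. By label, 2 controls and 3 knockouts were female. Each library is labelled as its own animal (M1 or F1, for example). The control libraries held 5701670 to 7697556 assigned reads and the knockout libraries 5789632 to 7355782. The table listed 23337 genes, of which 4773 had no read in any library and 13191 entered the tests. Levels are normalized read counts, given as mean ± SD over 4 control and 6 knockout libraries. Log2 fold changes (knockout over control) are given with their standard error.

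The targeted gene was examined first. Tbx5 (chromosome 5, 119832668 to 119885219, plus strand, GRCm38) was higher in the libraries labelled knockout than in the controls. Its level was 939 ± 125 normalized counts (SD, n = 4) in controls and 1952 ± 336 (SD, n = 6) in knockouts. The log2 fold change was 1.03 ± 0.14 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.78e-05), and every knockout library lay above every control library. An exact two-sided permutation test of the difference in mean log2 level, 1.02, gave p = 0.00476, the smallest that the 210 splits of 10 libraries can give. Exon 3 of the principal transcript (119838696 to 119838790) spans 95 bp, or 2.41% of its 3942 bp. A count over the whole gene therefore does not measure the deletion, and the direction of the Tbx5 count runs against what the knockout label alone would lead one to look for. Groups are therefore named by their labels throughout, and each direction given here rests on those labels.

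The main comparison asked which genes change in the adult left atrium after removal of Tbx5. In the libraries labelled knockout, 10 of 13 atrial identity genes fell, while 37 of 41 matrix, all 23 cell cycle and 13 of 14 macrophage genes rose. As lists, the last 3 did not pass with an estimated correlation (adjusted p = 0.132, adjusted p = 0.132 and adjusted p = 0.138). Gja5, the atrial and conduction-system connexin 40, fell from 1848 ± 287 to 90.8 ± 28.9 normalized counts, 20.7-fold lower. Myl7, the atrial regulatory myosin light chain, fell from 61119 ± 9804 to 3793 ± 1010. Eln, which encodes elastin, rose from 1577 ± 233 to 18983 ± 7266, and Cdk1, the mitotic kinase, from 15.1 ± 7.11 to 237 ± 89.9. In all, 5622 of 13191 genes passed an adjusted p of 0.05, 2741 higher and 2881 lower in the knockout libraries (edgeR quasi-likelihood test). In 3996 of them (71.1%) no knockout library overlapped any control library. Over all tested genes this held for 4128 (31.3%), where chance separates 0.952%. With scaling to library size alone, which moved the median log2 fold change of all tested genes to 0.14, the split was 3942 higher and 2020 lower. With a minimum absolute log2 fold change of 1, the count was 1533, and a test against a fold of 1.2 gave 3592. Across the libraries, the 10 most abundant genes of each took 19.3% to 20.9% of reads in controls and 10.9% to 14.4% in knockouts.

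**Figure D1:**
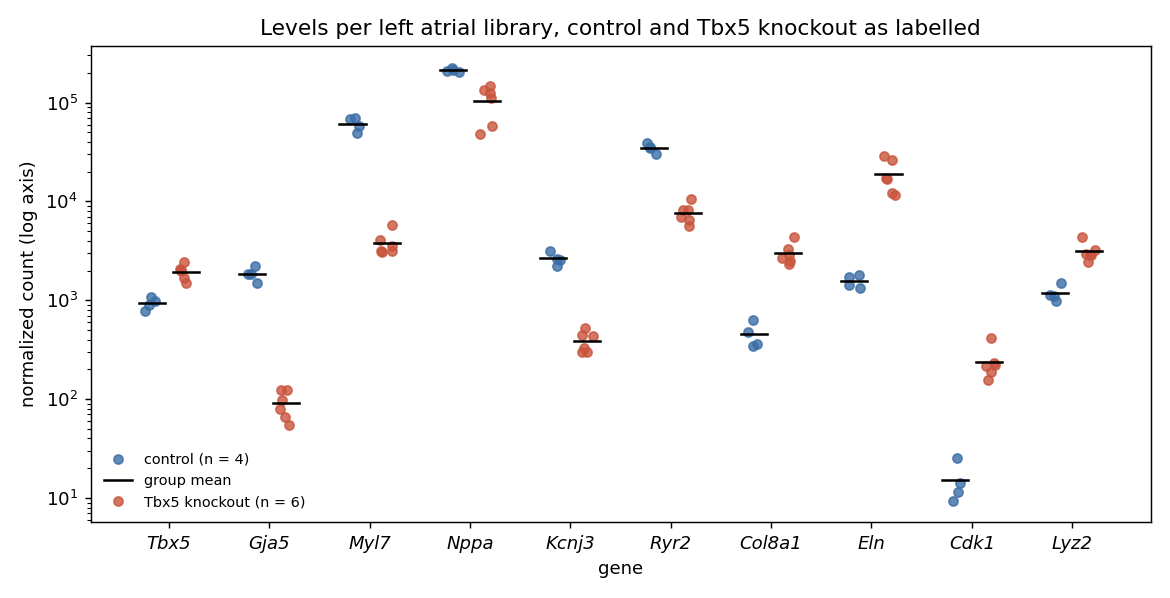
Normalized read counts on a log axis for 10 genes in each left atrial library, with control libraries in blue (n = 4), knockout libraries in red (n = 6) and black bars at the group means. Gja5, Myl7, Nppa, Kcnj3 and Ryr2 lay lower in every knockout library than in any control library, while Tbx5, Col8a1, Eln, Cdk1 and Lyz2 lay higher in every one.

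The 12 steepest falls under the naming rule included secreted, metabolic and muscle genes. Bmp3, a bone morphogenetic protein family ligand (chromosome 5, 98854415 to 98884396), fell from 99.9 ± 33.0 to 2.62 ± 1.76 normalized counts, a log2 fold change of -5.24 ± 0.34 (adjusted p = 1.97e-07). Fcamr, an Fc receptor for IgA and IgM, fell from 77.7 ± 9.99 to 2.46 ± 3.47, a log2 fold change of -5.06. Inmt, an indolethylamine methyltransferase, fell from 381 ± 336 to 14.5 ± 12.2, a log2 fold change of -4.78. The authors' deposited log2 fold changes were smaller in size, -2.22 for Fcamr and -2.68 for Inmt. The size of both falls is therefore uncertain, while their direction was the same. Cilp2 fell from 1364 ± 220 to 55.5 ± 17.5 and the SH3-binding kinase gene Sbk2 from 1269 ± 350 to 67.4 ± 20.7. Cmya5, which encodes the muscle protein myospryn, fell from 11787 ± 2947 to 847 ± 329. Ifltd1, Sds, Gpr158 and Mlana completed them, with log2 fold changes of -4.19, -3.75, -3.64 and -3.53.

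Among the 12 steepest rises, Col22a1, a fibril-associated collagen (chromosome 15, 71795795 to 72034227), rose from 1.64 ± 2.05 to 71.8 ± 37.3 normalized counts (log2 fold change 5.20 ± 0.61, adjusted p = 1.89e-05). Acta1, the skeletal alpha-actin, rose from 11.2 ± 5.15 to 347 ± 174. Tenascin C (Tnc) rose from 19.4 ± 6.14 to 581 ± 583, with knockout M2 at 1735 and the other knockout libraries between 176 and 531. Cthrc1, a secreted collagen-triple-helix repeat protein, rose from 6.93 ± 5.49 to 127 ± 94.6, again with knockout M2 highest at 313. The ventricular light chain Myl2 rose from 3.25 ± 2.28 to 87.6 ± 49.1. Ereg, a ligand of the epidermal growth factor receptor, rose by 3.83 ± 0.44 on the log2 scale. Pbk, Cdca3, Nuf2 and Cdk1, all genes of dividing cells, rose by log2 fold changes of 3.98, 3.92, 3.89 and 3.89. Hist1h2bm rose by 5.14, but histone genes exist in near-identical copies, so its reads may be shared with others and its value is uncertain.

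Of the 30 gene lists fixed before the data were examined, 25 had at least 5 tested members. On the preset correlation of 0.01 (camera, Benjamini-Hochberg over 25 lists), 14 lists passed an adjusted p of 0.05, 9 upward and 5 downward. With a correlation estimated for each list, 1 list passed, that of atrial cardiomyocyte identity. All 14 stayed past the threshold when any single library was left out.

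Atrial identity genes fell together. Of 13 tested members 10 fell, none rose and 3 did not pass (11 fell when adjusted over the list alone), with a median log2 fold change of -1.28 (adjusted p = 4.01e-21, and adjusted p = 0.00369 with an estimated correlation). Beside Gja5 and Myl7, the potassium channel subunit gene Kcnj3 fell from 2655 ± 379 to 389 ± 93.1 and the lipid transfer protein gene Stard10 from 4603 ± 866 to 847 ± 108. Nppa, the atrial natriuretic peptide gene, named here after its values were seen, fell from a mean of 213896 to 104127 normalized counts (log2 fold change -1.06). In the ventricular identity list 2 of 6 tested genes rose and none fell (the same counts adjusted over the list alone; median 0.60, adjusted p = 0.00694, and adjusted p = 0.132 with an estimated correlation). These were Myl2 and Myl3, a ventricular essential light chain gene that rose from 1039 ± 312 to 6945 ± 1443. Hey2 had a log2 fold change of 0.67 ± 0.30 (adjusted p = 0.0852) and Mpped2 of 0.54 ± 0.41 (adjusted p = 0.319).

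Ion channel and gap junction genes moved in both directions, with more falls than rises. In the list of sodium and pacemaker channels and connexins, 5 of 10 tested members fell and 1 rose, with the same counts adjusted over the list alone (median -0.89, adjusted p = 0.00113, and adjusted p = 0.22 with an estimated correlation). Beside Gja5, the connexin 43 gene Gja1 fell from 3812 ± 550 to 922 ± 407. Gjc1, connexin 45, rose from 167 ± 16.1 to 366 ± 89.3. Of 29 potassium channel genes 13 fell and 4 rose (15 and 4 adjusted over the list alone; median -0.46, adjusted p = 0.000662, and adjusted p = 0.138 with an estimated correlation). Kcnj5, which with Kcnj3 encodes the acetylcholine-activated channel, fell 4.84-fold. Kcnd2, a transient outward channel gene, fell from 456 ± 73.1 to 190 ± 42.6, and Abcc9, a subunit gene of ATP-sensitive channels, from 746 ± 46.5 to 383 ± 75.4.

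Calcium handling genes moved in both directions, with 14 of 30 lower, 4 higher and 12 not past the test (15 lower and 5 higher adjusted over the list alone). The median was -0.27 (adjusted p = 0.0220, and adjusted p = 0.374 with an estimated correlation). Ryr2, the sarcoplasmic calcium release channel, fell from 34855 ± 3468 to 7639 ± 1694, and Atp2a2, the sarcoplasmic calcium pump, from 94223 ± 6524 to 41045 ± 5918. Sarcolipin (Sln), an inhibitor of that pump, fell from 17263 ± 2929 to 7213 ± 1502. Casq1, the skeletal muscle calsequestrin, rose from 32.5 ± 10.9 to 231 ± 76.2. Across 11973 tested genes with a known exon length and GC content, the log2 fold change correlated with length (Spearman rho -0.23) and with GC content (rho 0.22), where genes are not independent replicates. With offsets for both, chosen after the data were seen, the calcium list had a median of -0.06 and an adjusted p of 0.304. The offsets were fitted without regard to group, so they cannot tell bias from a genotype change that follows length or GC content.

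Genes near human atrial fibrillation loci included 17 falls and 5 rises among 30 tested members (17 and 6 adjusted over the list alone; median -0.46, adjusted p = 9.06e-06, and adjusted p = 0.132 with an estimated correlation). Gja5, Kcnj5 and Nebl were among those with the smallest adjusted p, and several members also stand in the channel and sarcomere lists. Nebl, the Z-disc protein nebulette, fell from 1690 ± 353 to 475 ± 112. Among 31 cardiac transcription factors 11 fell and 4 rose, the same adjusted over the list alone, without a list-wide shift (adjusted p = 0.412). Hand2 rose from 103 ± 19.6 to 248 ± 35.7, whereas the Notch target Hey1 fell from 112 ± 17.2 to 56.2 ± 13.8. Mef2a fell by 0.59 ± 0.10 and Mef2c by 0.53 ± 0.10 on the log2 scale, but with the length and GC offsets their log2 fold changes were -0.17 and -0.06 and did not pass.

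Sarcomere and Z-disc genes divided. Of 27 tested members 11 rose, 6 fell and 10 did not pass (12 and 8 adjusted over the list alone), the median was 0.24 and the mean -0.07, and the list did not pass (adjusted p = 0.545). Titin (Ttn) fell from 448113 ± 62205 to 135951 ± 30313 normalized counts, the direction of Cmya5 and Nebl, while Mybpc3, cardiac myosin-binding protein C, rose from 13771 ± 773 to 33426 ± 2576. Cardiomyocyte stress genes rose in 9 of 14 cases and fell in 2, also adjusted over the list alone (median 1.15, adjusted p = 0.000535, and adjusted p = 0.132 with an estimated correlation). Ankrd1, a stretch-responsive nuclear cofactor, rose from 14288 ± 3903 to 51365 ± 11741, Fhl1 from 1429 ± 291 to 4953 ± 990 and Timp1, a metalloproteinase inhibitor, from 37.3 ± 19.7 to 292 ± 117. Immediate early genes rose in 11 of 17 cases, none fell, and the counts held when adjusted over the list alone (median 1.12, adjusted p = 0.000115, and adjusted p = 0.328 with an estimated correlation). Cyr61 rose from 234 ± 107 to 2336 ± 898, Atf3 from 68.3 ± 40.3 to 545 ± 280, Egr2 from 13.9 ± 6.28 to 157 ± 93.2 and Ier3 from 153 ± 11.9 to 502 ± 173.

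**Figure D2:**
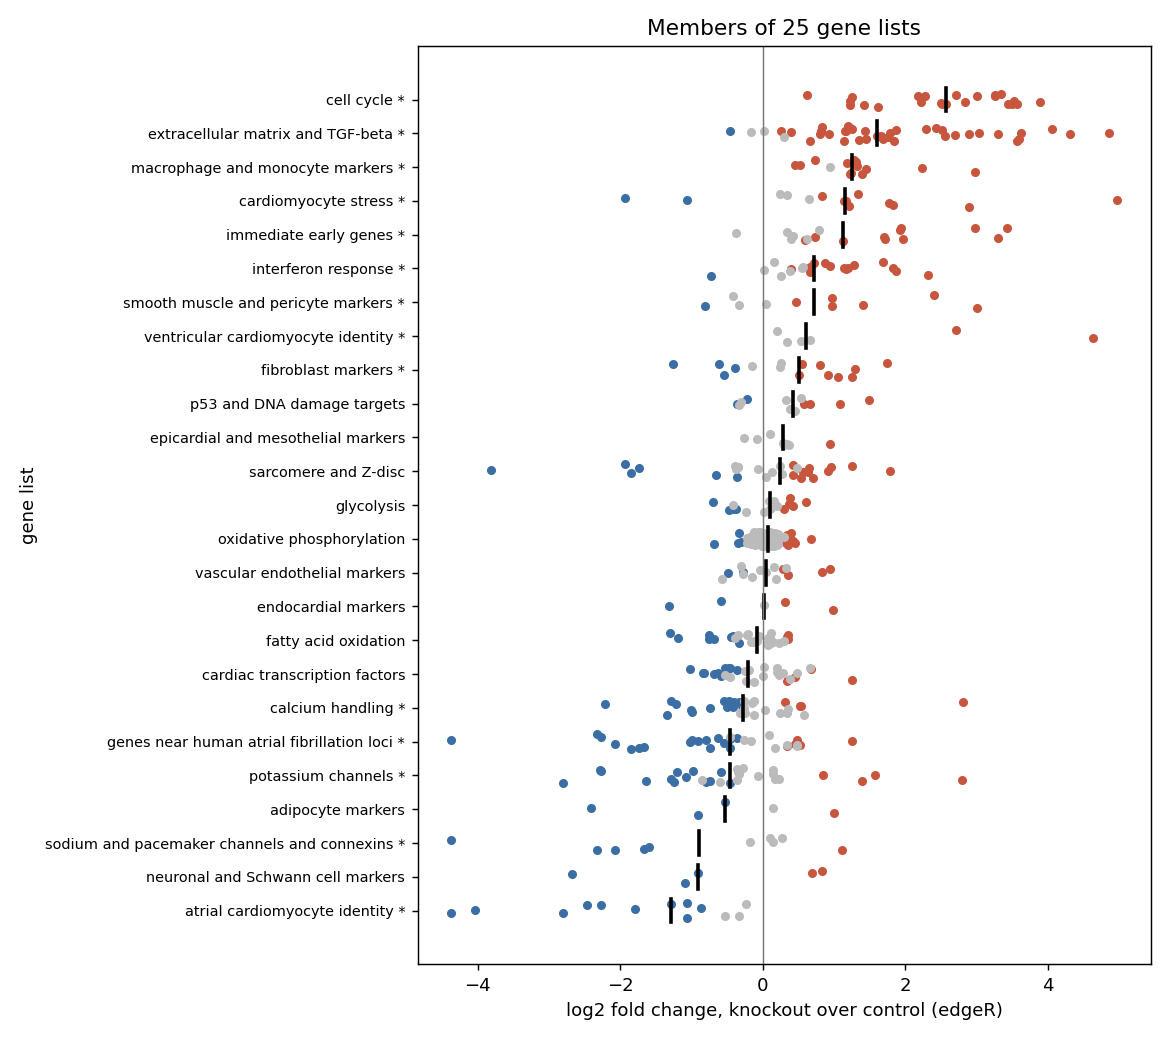
Log2 fold change, knockout over control, of each tested member of 25 gene lists, where red points rose and blue points fell at an adjusted p of 0.05, grey points did not pass, black bars mark list medians and asterisks mark the 14 lists past the camera test at the preset correlation. Cell cycle genes stood at a median of 2.57 and atrial identity genes at -1.28.

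Extracellular matrix and TGF-beta genes rose in 37 of 41 cases, with 1 fall and 3 not past the test, also adjusted over the list alone (median 1.60, adjusted p = 4.51e-26, and adjusted p = 0.132 with an estimated correlation). Beside Eln, the collagen gene Col8a1 rose from 455 ± 137 to 3010 ± 748, Col5a2 from 930 ± 123 to 5433 ± 1614 and Ltbp2, a latent TGF-beta binding protein family member, from 43.0 ± 6.26 to 544 ± 203. All 23 cell cycle genes rose, also adjusted over the list alone (median 2.57, adjusted p = 5.26e-22, and adjusted p = 0.132 with an estimated correlation). The mitotic cyclin Ccnb2 rose from 9.98 ± 4.36 to 107 ± 31.7, Ccna2 from 21.7 ± 11.9 to 258 ± 106 and the spindle factor Tpx2 from 13.3 ± 8.88 to 137 ± 45.2.

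Among markers of cells other than cardiomyocytes, the macrophage, fibroblast and smooth muscle lists passed upward at the preset correlation, but not with an estimated one. The vascular endothelial, endocardial and epicardial lists did not pass. Macrophage and monocyte markers rose in 13 of 14 cases (14 adjusted over the list alone; median 1.26, adjusted p = 6.38e-09, and adjusted p = 0.138 with an estimated correlation), with the lysozyme gene Lyz2 going from 1172 ± 213 to 3124 ± 644. The complement genes C1qa, C1qb and C1qc rose 2.34-fold, 2.50-fold and 2.36-fold. Fibroblast markers rose in 8 of 15 cases and fell in 4, also adjusted over the list alone (median 0.50, adjusted p = 0.0137, and adjusted p = 0.296 with an estimated correlation), among them Mfap4, Tcf21, Lum and Meox1 with rises of 2.38-fold, 2.44-fold, 2.07-fold and 3.34-fold. Smooth muscle and pericyte markers rose in 6 of 10 cases and fell in 1 (6 and 2 adjusted over the list alone; median 0.72, adjusted p = 0.0137, and adjusted p = 0.138 with an estimated correlation). Tagln rose from 82.6 ± 15.8 to 685 ± 259 and Acta2 from 281 ± 66.5 to 758 ± 257, both contractile genes that activated fibroblasts also express, and Cspg4 and Mcam each rose 1.96-fold. Vascular endothelial markers showed 4 rises and 2 falls among 15 (3 and 2 adjusted over the list alone; adjusted p = 0.545), with Emcn and Eng up 1.93-fold and 1.78-fold, Tie1 up 1.22-fold and Flt1 down 1.21-fold. Flt1 did not pass without control M1 (adjusted p = 0.0594), with library size only (log2 -0.13, adjusted p = 0.2) or with GC and length offsets (log2 -0.05, adjusted p = 0.627). Of 5 endocardial markers 2 rose, Vwf and Plvap, and 2 fell, Npr3 and Cytl1, also adjusted over the list alone. Plvap (adjusted p = 0.0462) did not pass with limma-voom (adjusted p = 0.0516), with the offsets (adjusted p = 0.233), or without control M1, M2 or F1 or knockout F2, M1 or M2 (adjusted p from 0.0505 to 0.105). The endocardial median of 0.02 and mean of -0.12 differed in sign, and the list did not pass (adjusted p = 0.995). Of 8 epicardial and mesothelial markers only Krt8 passed, 1.92-fold higher, also adjusted over the list alone (list adjusted p = 0.412), and not without both control F1 and knockout M3 (adjusted p = 0.0615). Krt18, Upk1b and Upk3b had log2 fold changes of 0.37, 0.34 and -0.27.

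Interferon response genes rose in 14 of 21 cases and fell in 1 (15 and 1 adjusted over the list alone; median 0.72, adjusted p = 8.03e-05, and adjusted p = 0.296 with an estimated correlation). Bst2 rose from 159 ± 28.1 to 364 ± 53.7, and Irf7, Isg15 and Oas1a rose 2.29-fold, 3.22-fold and 5.0-fold. Among 12 p53 targets 4 rose and 2 fell (4 and 3 adjusted over the list alone). The list did not pass with camera (adjusted p = 0.112) but passed with fry (adjusted p = 0.000906). The rises were Plk2 at 2.80-fold, Phlda3 at 2.12-fold, Bax at 1.59-fold and Aen at 1.49-fold.

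Energy metabolism showed no list-wide shift. In oxidative phosphorylation 59 of 73 genes did not pass, 10 rose and 4 fell (3 and 1 adjusted over the list alone; list adjusted p = 0.412). Cox6c rose from 3304 ± 213 to 5365 ± 858, Cyc1 and Atp5j2 rose 1.34-fold and 1.37-fold, and Cox7a1 fell from 4784 ± 527 to 3028 ± 423. Fatty acid oxidation had 8 falls and 3 rises among 31 genes (7 and 2 adjusted over the list alone; list adjusted p = 0.427). Ppargc1a, a coactivator of mitochondrial gene expression, fell from 859 ± 156 to 353 ± 67.1, and Acsl1, Cd36 and Ppara fell 1.61-fold, 1.68-fold and 1.68-fold. Of 17 glycolysis genes 5 rose and 4 fell, also adjusted over the list alone (list adjusted p = 0.741). Pgam2 and Pfkm fell 1.62-fold and 1.39-fold, whereas Pgk1 and Pfkp rose 1.52-fold and 1.34-fold.

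Small lists gave few members. Of 5 adipocyte markers 3 fell (Plin4, Cfd and Thrsp) and 1 rose (Cidea), and of 5 neuronal and Schwann cell markers 3 fell, Dbh and Cdh19 among them, and 2 rose (S100b and Uchl1, the latter named after its values were seen). Cfd did not pass with DESeq2 (adjusted p = 0.0750), limma-voom (adjusted p = 0.431), the robust fit or the replicate block, or without control M1 or M2 or knockout F1, F2 or F3, with a log2 fold change of -1.40 without control M2. Thrsp did not pass with library size only (adjusted p = 0.11) or without control M1 or M2 or knockout F1 or F2 (adjusted p from 0.0619 to 0.169). S100b did not pass with the offsets (adjusted p = 0.0684) or without control F1 or F2 or knockout F2, F3 or M2 (adjusted p from 0.0525 to 0.0926). Both counts held when adjusted over the list alone, and neither list passed with camera (adjusted p = 0.741 and adjusted p = 0.381). With fry the neuronal list passed (adjusted p = 0.00397) and the adipocyte list did not (adjusted p = 0.446). Dbh, dopamine beta-hydroxylase of sympathetic neurons, fell from 25.1 ± 9.49 to 3.85 ± 1.71. The lists of neutrophil, lymphocyte, erythroid, sinus node and lung epithelial markers had 2, 1, 1, 4 and 0 tested members and no list test. Both neutrophil genes rose, S100a9 from 5.71 ± 2.75 to 12.6 ± 4.29 and Csf3r from 9.04 ± 4.48 to 16.2 ± 2.92, but neither call held under every setting. S100a9 did not pass with limma-voom (adjusted p = 0.0555) or the replicate block (adjusted p = 0.0720), or without control M1 or F1 or knockout F1, F2, F3 or M2 (adjusted p from 0.0513 to 0.104). Csf3r did not pass with DESeq2 (adjusted p = 0.0559), the block (adjusted p = 0.0740) or the offsets (adjusted p = 0.0781), or without control M1, M2 or F1 or knockout F1, F2, M1 or M2 (adjusted p from 0.0505 to 0.134). Cd4 had levels of 6.21 ± 2.86 and 13.4 ± 6.12 (adjusted p = 0.0544, though it passed adjusted over the list alone), and Alas2 of 103 ± 43.5 and 166 ± 89.8 (adjusted p = 0.192, also not past adjusted over the list alone). Of the sinus node genes Cacna1d and Tbx3 fell 1.67-fold and 1.76-fold, also adjusted over the list alone, although Tbx3 did not pass with library size only (adjusted p = 0.0510) or without control M1, F1 or F2 (adjusted p from 0.0583 to 0.0809), and Tbx18 had a log2 fold change of 0.39 (adjusted p = 0.14).

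Both sexes were sampled in both groups, so the effect of genotype was also fitted within each labelled sex. Sex-linked counts ran opposite to the labelled sex in 4 of 4 control libraries and matched it in 6 of 6 knockout libraries. Xist, expressed from the inactive X chromosome of females, stood at 6820 and 5250 normalized counts in the controls labelled male, M1 and M2, and at 138 and 9.41 in the controls labelled female, F1 and F2. Ddx3y, on the Y chromosome, stood at 1301 and 998 in the controls labelled female and had no read in those labelled male. The labels were kept as given. The comparisons within a sex thus set knockout libraries of 1 labelled sex against controls whose sex-linked counts were those of the other.

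**Figure D3:**
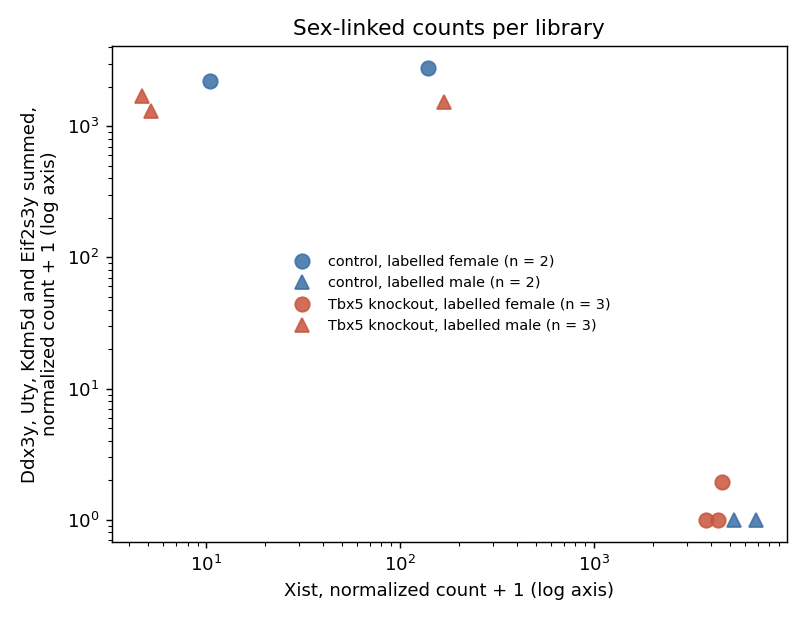
Xist against the summed counts of Ddx3y, Uty, Kdm5d and Eif2s3y in each library, both as normalized count + 1 on log axes, with circles labelled female, triangles labelled male, controls in blue and knockouts in red. The 2 controls labelled male lie beside the knockouts labelled female, and the 2 controls labelled female beside the knockouts labelled male.

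Within the labelled sexes, 3720 genes passed in females (1779 higher and 1941 lower in knockouts) and 3437 in males (1693 higher and 1744 lower). Of the 2383 genes past the threshold in both, 2364 had the same direction. The overlap held 1131 genes higher and 1233 lower in both, against 228 and 257 for independent lists, with separate libraries on both sides of each contrast and one shared estimate of spread. Leaving out control F1 or F2 took the female count to 1552 or 2141, and the female libraries alone gave 4957. The male count was 1159, 2232 or 2261 without control M1, control M2 or knockout M2, and 2061 from the male libraries alone.

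The difference between the labelled sexes in the genotype effect passed the threshold for 27 genes, 19 with a higher and 8 with a lower log2 fold change in libraries labelled male. Both the count and its directions rest on the control labels, which ran opposite to the sex-linked counts. With such labels, a sex difference that is alike in both groups also enters the interaction. The test therefore cannot tell it from a genotype effect that depends on sex. Xist was among the 27 genes (interaction log2 -12.6, adjusted p = 0.00322). The 4 smallest adjusted p belonged to the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, with means of 1149, 569, 277 and 484 normalized counts in controls labelled female and of 0 in those labelled male. In knockouts their means were 639, 336, 145 and 390 in males and at most 0.316 in females. C7, a complement component gene, had means of 736 and 79.4 in controls labelled female and male, and of 27.7 and 146 in knockouts labelled female and male (interaction log2 5.62 ± 0.49, adjusted p = 0.000113). Cilp, a cartilage matrix protein gene, had means of 87.4 and 365 in the controls and 584 and 498 in the knockouts, in the same order (interaction log2 -2.29 ± 0.26, adjusted p = 0.00167). For both genes the sign of the interaction holds only for the control sexes as labelled. The count of 27 became 7 without control F2, 10 to 13 without any other control or without knockout F1, F2 or F3, and 77 without knockout M3. It was 114 without a low-count filter and 80 with DESeq2. Across both groups, the labelled sexes differed in 2 genes, Klf15 and Jun, both lower in libraries labelled male (log2 -0.80 ± 0.11 and -0.89 ± 0.13, each with an adjusted p of 0.0493). Libraries labelled male here pool controls with the sex-linked counts of females and knockouts with those of males. Neither Xist nor the 4 Y-linked genes passed, so this comparison does not measure sex as read from those counts. With RLE scaling the count of 2 became 0. It was also 0 without control M2 or F1 or knockout F2, F3, M1 or M2, 1 without control M1, and 6 without knockout F1 or M3, and 743 genes had an unadjusted p under 0.05 in the main test.

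The authors' deposited table of a DESeq2 comparison holds an adjusted p for 15796 genes, 5776 of them under 0.05, with 2960 higher and 2816 lower in knockouts. Among the 13177 genes in both tests, 5347 were past the threshold in the authors' deposited table and in edgeR, all with the same direction. A further 169 passed in the authors' deposited table alone and 273 in edgeR alone.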

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

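All tests of explanations in this part were chosen after the results were seen. Single values far from the rest of their group were searched among the named genes and the library totals with a gap test. It picks about 1 group in 20 by chance if values are normally distributed. Of 260 groups, 23 had such a value, against 13 by chance on that assumption. The counts were not put on a log scale and the genes are not independent, so the 13 is only a rough guide.

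Knockout M2 held 9 of them. Its normalized counts stood above the other 5 knockout libraries for Tnc (1735), Cthrc1 (313), Cdca3 (206), Cdk1 (412), Ereg (172), Timp1 (520), C1qa (1769), Pfkp (706) and Tpx2 (224). These include members of the matrix, cell cycle and macrophage lists, which passed upward at the preset correlation but not with an estimated one (adjusted p = 0.132, adjusted p = 0.132 and adjusted p = 0.138). Knockout M1 held 6, with high values for Gjc1 (534), Mef2a (633), Mpped2 (31.1), Tie1 (1125) and Cacna1d (98.5) and a low value for Pgk1 (133). Knockout F2 stood above the rest for Col22a1 (143) and Mfap4 (2874), and knockout M3 for Myl7 (5719) and Mef2c (723). Among controls, F1 was high for Npr3 (4999) and Alas2 (168), F2 for Ifltd1 (365) and M2 for Tbx18 (185).

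The interaction test of labelled sex and genotype passed for 6 named genes. These were C7 (5.62, male minus female as labelled, log2), Cilp (-2.29) and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, whose means in controls labelled female were 1149, 569, 277 and 484 normalized counts. These differences and their signs hold only for the control sexes as labelled. They cannot be told from sex differences alike in both groups, because the control labels ran opposite to the sex-linked counts.

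Those Y-linked values belong to a pattern in which sex-linked counts ran opposite to the label in the controls. RNA of both sexes mixed in the controls labelled male would leave their own Y-linked reads in place, and the 4 Y-linked genes had 0 reads summed over both libraries, which argues against mixing there. The controls labelled male held 5767 and 6201 Xist reads beside these 0, so their labelled sex is not the one their counts show. How this arose stays open, an exchange of the male and female titles within the controls included. Such an exchange needs all 4 control libraries to differ from their label, as they do. That count is the observation that raised it, so it is not a separate test of it. No biological explanation was tested. Fits with the control titles exchanged were run once after the data were seen and are not used, because they group libraries by their own counts. In them fewer genes passed the interaction than as labelled, more genes differed between the sexes, and the interaction of Cilp had the opposite sign. Control F1 and knockout M3 held 119 and 153 Xist reads beside 1125 and 656 reads of Ddx3y, where the other libraries with more than 1 Ddx3y read held 4 to 9 Xist reads, and without both of them 4716 genes passed for genotype. Knockout F3 held 1 Ddx3y read and 4802 Xist reads.

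A further pattern is the higher Tbx5 count in libraries labelled knockout. An exchange of the labels of the 2 groups would put the Tbx5-dependent genes Gja5 and Nppa higher in the libraries labelled knockout, but both fell, and the higher of their log2 fold changes was -1.06. Scaling between libraries would remove the difference under some scaling, but the lowest over TMM, RLE, upper-quartile and library-size scaling was 1.02. A higher level of transcripts without exon 3 after its deletion stays open as a biological explanation, and counts by exon were not used here. Overlapping or antisense reads at the locus also stay open, since the strand setting is not given.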

How the results depend on the processing

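The settings added after the data were seen are library size only, the robust fit, leaving out control F1 and knockout M3 together, and the GC and length offsets. The count for genotype stayed within 1.5 times 5622 under every setting except 2. It was 1533 (826 higher, 707 lower) with an absolute log2 fold change above 1 and 3592 (1717 higher, 1875 lower) in the test against a fold of 1.2. Leaving out each library in turn gave 4709 to 6085 genes (2408 to 3042 higher, 2301 to 3043 lower). With a replicate block the count was 5411 (2599 higher, 2812 lower). Same-numbered libraries had correlations of their deviations from group means of -0.04 (M1), 0.17 (M2), -0.13 (F1) and -0.05 (F2), and only M2 correlated best with its own number. These values show no pairing by number. They cannot exclude it, because same-numbered control and knockout libraries had opposite sex-linked counts. The Tbx5 difference kept its direction and its p of 0.00476 under all scalings, between 1.02 and 1.16. The number of lists past the threshold was 14 in every leave-one-out fit, 1 with an estimated correlation and 16 with fry. For the sex by genotype interaction it was 114 genes without a filter, 13 with at least 50 counts in 4 libraries, 80 with DESeq2, and 7 to 77 leaving out each library. The sex difference gave 0 genes with RLE, 35 without a filter and 0 to 6 leaving out each library, 0 without control M2 or F1 or knockout F2, F3, M1 or M2. Females gave 1552 to 4519 genes and males 1159 to 4008 leaving out each library, and the libraries of that sex alone gave 4957 and 2061. Fits with a library left out have fewer samples, but sample number alone does not set their counts. For genotype, leaving out 1 knockout library gave from 5016 genes (without F2) to 6085 (without M1). The cause of these and the other changes was not tested.

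Among named genes, 2668 comparisons with an alternative kept direction and side of the threshold, 73 lost the call and 19 gained one, and none changed sign. Among lists 568 kept both, 14 lost the call (13 with an estimated correlation, 1 with GC and length offsets) and 2 gained one with fry. The 2 were p53 targets and neuronal and Schwann cell markers. The median of a list changed sign in 13 cases, each in a list not past the threshold on either side, and the cause was not tested. Endocardial markers had a median of -0.0169 with limma-voom, -0.0142 without control F1 and knockout M3, -0.0167 with GC and length offsets, and -0.14 (without knockout M1) to 0.12 (without control M1) leaving out each library, with -0.06 without control F1. Fatty acid oxidation had 0.0625 with limma-voom, 0.0605 with library size only, and -0.0940 (without knockout M3) to 0.0770 (without control M1) leaving out each library. Oxidative phosphorylation had -0.0265 with the replicate block and -0.0941 with the offsets, glycolysis -0.0275 with the offsets, vascular endothelial markers -0.00308 with the replicate block, and neuronal markers 0.0205 without a filter. Depth limits the precision of genes with few reads, and it was not varied. At the same depth the simulated test recovered 70.1% of 2-fold changes for genotype and 13.4% for the interaction. That simulation changed 200 of 13191 genes, far fewer than the 5622 called for genotype, so these shares need not be those of the real test.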

Other observations

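The tests of gene groups by symbol, the GC and length offsets, the tests of explanations and the counts of other splits were chosen after the results were seen, whereas the gene lists and the sex difference with its RLE and leave-one-out settings were set before. Beside the fixed lists, genes sharing the leading letters of their symbol were tested as groups, 150 groups with at least 10 tested members each. Some groups share members with the fixed lists, such as Col8a1 with the matrix list and Mcm5 with the cell cycle list. Such groups are not separate evidence from those lists. On the preset correlation (camera, Benjamini-Hochberg) 12 groups passed, 7 upward and 5 downward, each with the same direction under RLE, upper-quartile and library-size scaling. All 12 also passed under these 3 scalings, except that the Tbc group passed in 1 of them, and 0 passed with an estimated correlation (adjusted p = 0.802 for each of the 12). Histone genes rose in 45 of 54 cases and fell in 3 (median log2 fold change 2.65, adjusted p = 4.84e-22). Hist2h2bb went from 230 ± 29.4 to 902 ± 169 normalized counts and Hist1h1d from 73.7 ± 19.2 to 371 ± 99.6 (SD, n = 4 and 6). Reads of near-identical histone copies may be shared, so single members are uncertain, and with GC and length offsets the median was 2.39. Collagen genes rose in 26 of 38 cases and fell in 6. The Mcm genes, most of which encode the replicative helicase, rose in 7 of 10 cases, with Mcm5 going from 43.8 ± 24.0 to 213 ± 52.9. All 10 tested Psmb genes, which encode proteasome beta subunits, rose, by a median of 0.53, but this group did not pass with GC and length offsets (adjusted p = 0.133). Annexins rose in 7 of 10 cases, among them Anxa2 from 1031 ± 213 to 2772 ± 409, but did not pass with the offsets either (adjusted p = 0.115). Ribosomal protein genes of the large subunit rose in 13 of 36 cases and also did not pass with the offsets (adjusted p = 0.382). Symbols beginning with Cd, largely surface antigens, rose in 28 of 58 cases and fell in 3, with Cd44 going from 312 ± 106 to 969 ± 219.

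Of the groups that fell, gamma-protocadherin genes were lower in 11 of 12 cases (median -0.88, adjusted p = 8.89e-05). Pcdhga12 went from 191 ± 10.5 to 76.4 ± 14.9, although members of this cluster share constant exons, so their reads are not separate evidence. Genes of A-kinase anchoring proteins, which hold protein kinase A near its targets, fell in 11 of 13 cases and rose in 1 (median -0.59, adjusted p = 0.000358). Akap6, of the cardiomyocyte nuclear envelope, went from 4271 ± 625 to 2020 ± 296 and Akap9 from 1077 ± 180 to 308 ± 73.9, and the group passed with the offsets (adjusted p = 0.00511). Genes of the Tbc1d group of Rab GTPase-activating proteins fell in 10 of 27 cases and rose in 2, with Tbc1d4, which acts in glucose transporter traffic, going from 2133 ± 178 to 780 ± 62.5 and Tbc1d1 from 2121 ± 136 to 827 ± 76.4. Centrosomal Cep genes fell in 11 of 20 cases and Abca transporters in 5 of 11, and neither passed with the offsets (adjusted p = 0.335 and adjusted p = 0.200).

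Atrial identity genes were lower in knockout libraries as a group, and technical explanations were set against this. Ventricular tissue in the knockout samples would raise the ventricular light chains Myl2 and Myl3 by similar amounts, but the rise of Myl2 (84.3 normalized counts) was 1.43% of that of Myl3 (5906). A lower share of cardiomyocytes would lower sarcomere genes with the atrial genes, but 11 of 27 sarcomere and Z-disc genes rose, which argues against it as the whole cause, while 6 fell, Ttn and Nebl among them, as a lower share would have it. With offsets for GC content and gene length the list kept its call, with a median of -1.42. Loss of Tbx5 may explain the pattern, but Cre activity and tamoxifen stay open beside it, since the labels do not say whether the controls had either.

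Counts from other splits of the 10 libraries were set beside the real ones. For genotype, 1 of 100 drawn splits into 4 and 6 gave at least 5622 genes, the real one itself. The highest of the others gave 1 gene. Every other split puts controls and knockouts together on at least 1 side. This adds the group difference to the spread and lowers the count. The real split thus ranked first, but these counts do not exclude chance. For labelled sex, splits into 5 and 5 with the group as a covariate were drawn in 2 sets of 100. In each set 2 of 100 splits, the real one included, gave at least the 2 genes of the real one. In the first set drawn the other gave 14 genes and set the controls labelled male and the knockouts labelled female against the rest, so that the controls were divided as for the real split but with their sexes exchanged. In the second it gave 599 genes and set the controls and knockout M1 against the rest. With the group as a covariate that split contrasts 1 library with the other 5 knockouts. The same contrast for each other knockout, over both sets, gave far fewer genes, though each such count rests on 1 library. Knockout M1 correlated with the other knockouts at 0.964 to 0.969, the low end of the within-group range of 0.964 to 0.986. Leaving it out gave 6085 genes for genotype, the highest of the fits without 1 library. Why knockout M1 differs was not tested. The share of splits as large is under 0.05 in both sets, but the 2 genes passed at an adjusted p of 0.0493, and 0 genes passed with RLE or without control M2 or F1 or knockout F2, F3, M1 or M2. The count of 2 is therefore not taken as a difference between the sexes.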
